A study of Mus musculus with 10 samples.

How the data were processed

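Gene expression was measured in whole lungs of 10 mouse embryos at E18.5, late in gestation, with 1 Affymetrix mouse gene array per lung. Per the labels, 5 lungs came from Shh-Cre controls and 5 from embryos in which Shh-Cre, a recombinase active in the lung epithelium, deleted floxed Hdac3. The cross in the labels' protocols joined Hdac3 fl/fl females with Hdac3 fl/+ Shh-Cre males, and the control label does not give the Hdac3 alleles. Each embryo of this cross inherits a floxed allele from its mother. A control of this cross that carries Shh-Cre would therefore be Hdac3 fl/+ and heterozygous for the deletion in its epithelium. The labels call the samples biological replicates, and the whole lung was profiled, so unrecombined mesenchymal, endothelial and blood cells contribute to each value. Per the labels' protocols, 100 ng of total RNA was reverse transcribed from a poly(T) primer and amplified by in vitro transcription. A probe set for a microRNA precursor therefore reads polyadenylated RNA that contains the precursor, not the mature microRNA.

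The values are log2 probe set levels as the authors deposited them. Per the submitters' processing notes, oligo, RMA and limma were used, with no versions given. The genome build behind the array's annotation, and any rule by which rows were kept, are not given in the sources used here. The scanner files were not used here, so the background correction was not repeated. The table held 24888 probe sets with no missing value, from 3.526 to 13.611, and the sample medians lay between 7.428 and 7.461. No sample's values were identical to another's, and the correlation between samples ran from 0.9851 to 0.9953. For arrays, the number of lungs limits the precision; the median standard error of a log2 change was 0.066.

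Probe sets were named through the platform's annotation table. It gave 1 gene symbol for 18922 probe sets, several for 1343 and none for 4623. Of the probe sets with 1 symbol, 18790 matched the GRCm38.p6 gene table by gene ID, and 0 symbols needed an update. That table was used only for names, transcript types and the order of neighbouring genes. Each gene was represented by the probe set with the highest mean over all samples, which gave 17919 genes; 793 genes had more than 1 probe set. List members were matched by symbol, and through a synonym only where the listed name is no current symbol of that table. Mir17hg, H19, Trf and Loxl2 shared their probe sets with other gene names and have no values of their own here.

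The knockout was compared with the control by limma (lmFit and eBayes, default prior, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Adjusted p values of genes below are limma's unless another test is named. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 35 lists of at least 3 measured members. The sex-linked list was described and not tested. For 14 cell type lists, the mean level per sample was also compared by a two-sided exact permutation test over all 252 assignments, whose smallest p is 0.0079.

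The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Hdac3, Tgfbr2 and Tgfb1. It also named the 12 largest rises and 12 largest falls among called genes whose 5 knockout values all lay on that side of the control mean, without predicted or unnamed genes, microRNAs, small nucleolar RNAs and immune receptor segments. From each list it took up to 4 called members with the smallest p, or 2 members where fewer than 2 were called. Other genes named below were chosen after their values were seen and are introduced as such.

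Both groups carry the replicate numbers 1 to 5, and no label says what a number shares. The deviations of same-numbered samples from their group means correlated at 0.319, 0.154, 0.183, 0.485 and 0.36, against a median of -0.0829 and a highest value of 0.33 between control and knockout samples of different numbers; 3 of the 5 same-numbered values lie below that highest value. For 7 of 10 samples the best match in the other group had the same number. The numbers were therefore taken to pair the samples, and values with the replicate number as a block are given where the block changes the call of a named gene or the count of a list, or moves another count by over 1.5 times. The pairing comes from the data and not from the labels. On the second principal component (22.1% of the variance), controls 1 to 3 lay from 8.89 to 14.49 and controls 4 and 5 at -2.56 and -2.84, while knockouts 1 to 3 lay from -0.64 to 3.54 and knockouts 4 and 5 at -13.23 and -17.03. The labels name no batch. The correlations between different numbers were taken within and across these sets together. A difference between the sets alone could raise the same-numbered correlations, and this was not told apart from pairing. The sex-linked genes were also kept in these correlations. Control 1 and knockout 1 were the only lungs with high Xist (11.21 and 11.47), and both had low Y-linked means (4.72 and 4.73). Their shared sex-linked levels could raise the value of 0.319 for number 1, and this was not told apart from pairing either. After this was seen, numbers 1 to 3 and 4 to 5 were also used as a block and as subsets, and list means were also tested by limma with and without the replicate block, and without each list's member of the largest change.

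On simulated arrays with the means and spreads of the 17919 genes, the fit recovered 31.3% of genes changed by 0.3 on the log2 scale, 85.1% at 0.6 and 100% at 1, with 6 false calls among 151. A simulated list of 25 genes shifted by 0.15 was called, and 0 of 30 unshifted lists were. These simulated genes varied independently, which real genes do not. Alternatives covered the rows tested, the background floor, normalization, the prior, array weights, the replicate block, embryo sex, blood content, the probe set chosen, the thresholds, the test and each sample left out in turn. R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.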

Results

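The series compares 5 lungs with epithelial deletion of Hdac3, a histone deacetylase that acts in the NCoR/SMRT corepressor complexes, with 5 Shh-Cre control lungs at E18.5. The question, from what is known of the study, is which genes depend on epithelial Hdac3 as the alveolar epithelium matures, with TGF-beta signalling and the miR-17-92 microRNA cluster as its focus.

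Hdac3 itself fell by 0.31 ± 0.07 (SE) on the log2 scale, to 80.4% of the control level. The control mean was 10.81 ± 0.10 (SD, n = 5) and the knockout mean 10.50 ± 0.11 (SD, n = 5), and all knockout lungs lay below all control lungs (exact permutation p = 0.00794, two-sided, limma adjusted p = 0.0203). The array has 1 Hdac3 probe set; whether it lies in the deleted part is not given in the sources used here, and whole lung retains the Hdac3 of unrecombined cells. The labels do not give the Hdac3 alleles of the controls. Shh-Cre controls from the cross given above would be heterozygous for the deletion in the epithelium, and this holds for each comparison below. The call was lost without control 2 (adjusted p = 0.0526) or without control 5 (adjusted p = 0.0545). Among 14 measured chromosomal neighbours of Hdac3, 0 were called by limma (1 at an unadjusted p under 0.05), and Fgf1 had a log2 change of -0.32 (adjusted p = 0.138, and 0.0388 with the replicate block).

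Of 17919 genes, 559 differed between knockout and control, 276 higher and 283 lower. With the replicate number as a block the count was 846, with 409 higher and 437 lower, and 517 genes were called in the same direction by both fits. Lungs numbered 1 to 3 stood apart from those numbered 4 and 5 in both groups on the second principal component, and with these sets as a block, chosen after seeing the data, 910 genes were called. The changes were mostly small: 139 called genes reached a fold of 1.5, and 42 reached a fold of 2, with 27 of these higher and 15 lower.

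Plac1, a gene known from placental trophoblast, rose most among the genes the rule named, from 6.41 ± 0.23 to 8.98 ± 0.46 (SD, n = 5 per group). This is a log2 change of 2.57 ± 0.19 (SE, adjusted p = 1.71e-05). The keratins Krt15 and Krt18 rose by 1.75 ± 0.15 and 1.34 ± 0.07, and Cldn4, a tight junction claudin, by 1.95 ± 0.32. The aspartic protease gene Cym rose by 1.70, Psca by 1.45, the muscle enolase gene Eno3 by 1.11 and Mucl3 by 1.06. The control mean of Psca (6.23) lay under the 20th percentile of all values (6.3). With values floored there Psca rose by 1.33 and was still called (adjusted p = 0.000584). The neutrophil chemokine gene Cxcl3 was called higher (adjusted p = 0.00172), but its means of 4.40 and 6.45 lay under and just above the 20th percentile of all values (6.3), and it was not called with values floored there (log2 change 0.35, adjusted p = 0.655). Of the 12 largest rises, 3 serve glutathione or quinone metabolism. Gclc, of glutathione synthesis, rose by 1.16 ± 0.23 and Nqo1, a quinone reductase, by 1.04 ± 0.12. Slc7a11, the cystine transporter, was also called higher (adjusted p = 0.0201), but both its means (4.93 and 6.18) lay under 6.3, and it was not called with values floored there (adjusted p = 0.682).

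Retnla, a secreted resistin-like protein, had the largest fall among the genes named, by 2.27 ± 0.17 (SE) on the log2 scale (adjusted p = 1.75e-05). Its mean went from 11.29 ± 0.12 to 9.01 ± 0.45 (SD, n = 5 per group). Pon1, a paraoxonase, fell by 1.60 ± 0.22. Hc, which encodes complement component C5, fell by 1.74 ± 0.24. Cblif, the gastric intrinsic factor, fell by 1.76, Rasgrf2 by 1.27, Platr22 by 1.13 and Akr1c14 by 1.05. Reg3g, an antimicrobial lectin, and Pnliprp1 were called lower, with means that went from 7.40 to 5.46 and from 6.73 to 5.39, so that their size is uncertain. With values floored at 6.3, Reg3g had a log2 change of -1.10 and was not called (adjusted p = 0.142), and Pnliprp1 had -0.43, at the threshold (adjusted p = 0.05). The remaining largest falls, Chad, Gabrp and Scgb3a2, belong to the club cell list.

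**Figure D1:**
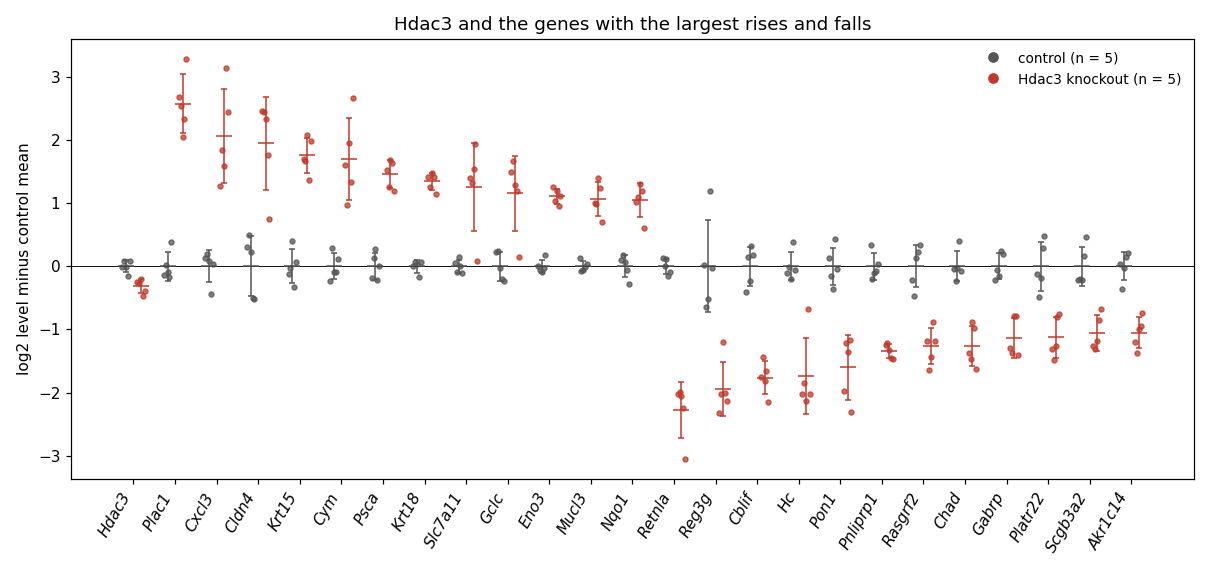
Each point is 1 lung's log2 level minus the control mean of that gene, in grey for controls and red for Hdac3 knockouts (n = 5 each); dashes are group means and bars SD. Hdac3 fell by 0.31, Plac1 rose by 2.57 and Retnla fell by 2.27; for Slc7a11 and Gclc, knockout 5 lies near the controls.

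Epithelial cell lists moved in different directions. Of 17 measured club and secretory markers, 5 fell and 3 rose. Scgb3a2, a secretoglobin of airway secretory cells, fell by 1.06 ± 0.16 (SE), Chad by 1.26, Gabrp by 1.13 and Aldh1a7 by 0.58. The rule named these 4 for their smallest p, and all are falls. Among the 3 rises was Gsta3 (0.67, adjusted p = 0.0027), named here after its values were seen. The list was lower as a whole (camera adjusted p = 0.0116; adjusted p = 0.549 with an estimated correlation), a call lost without knockout 1 (adjusted p = 0.0518). With the replicate block 6 fell and 4 rose, and adjusted over the list alone, 8 fell and 4 rose.

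Of 25 ciliated cell markers, 5 fell and 1 rose; with the block 6 fell and 1 rose, and adjusted over the list alone, 8 fell and 2 rose. The axonemal dynein genes Dnah11, Dnah9 and Dnaic2 fell by 0.36, 0.27 and 0.26, and Myb, a regulator of multiciliated cells, fell by 0.46. The list was lower (camera adjusted p = 0.00967; adjusted p = 0.549 with an estimated correlation), but not among genes above the median level (adjusted p = 0.541) or with only numbers 4 and 5 (0.14). Of 9 basal cell markers, Krt15 rose by 1.75 and Aqp3 by 0.68, and Pdpn fell by 0.52; adjusted over the list alone, 2 rose and 1 fell. The basal list was not called by camera (adjusted p = 0.129; adjusted p = 0.549 with an estimated correlation).

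Of 26 markers of AT1 cells, the flat gas-exchange cells, 4 fell and 2 rose. The basement membrane collagens Col4a3 and Col4a4 fell by 0.70 ± 0.07 and 0.50 ± 0.08 (SE), and Pdpn by 0.52 ± 0.10. Gprc5a rose by 0.34 ± 0.05. The list was not shifted (camera adjusted p = 0.659). With the replicate block, and also without knockout 5, 4 rose and 4 fell, and adjusted over the list alone 5 rose and 5 fell.

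Of 24 markers of AT2 cells, which make surfactant, 2 rose and 1 fell. Etv5, a transcription factor of AT2 cells, rose by 0.61 ± 0.07 (SE) and Lpcat1, an enzyme of surfactant phospholipid synthesis, by 0.34 ± 0.05, while Cpm fell by 0.53 ± 0.08. The list was higher (camera adjusted p = 0.0453; adjusted p = 0.746 with an estimated correlation). Without knockout 4 it was not (adjusted p = 0.269), and leaving out control 3, control 4, knockout 1, knockout 2 or knockout 3 also ended the call, at adjusted p from 0.0653 to 0.139. So did genes above the median level (0.0927), values floored at 6.3 (0.0501) and only numbers 4 and 5 (0.608). With the replicate block 4 rose and 1 fell, without knockout 5 (an omission chosen after seeing the data) 7 rose and 1 fell, and adjusted over the list alone 7 rose and 2 fell. Of 21 distal progenitor and lineage regulators, 0 rose and 2 fell, namely Fgfr2 by 0.29 and Foxa1 by 0.42; with the block 1 rose, Klf5 (0.23, adjusted p = 0.0404), and 2 fell, and adjusted over the list alone, 3 rose and 2 fell.

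Of 23 fibroblast markers, Ces1d alone fell, by 0.31 (1 adjusted over the list alone). That list was lower (camera adjusted p = 0.0187; adjusted p = 0.549 with an estimated correlation), but not without control 4 (adjusted p = 0.0824), knockout 1 (0.0737) or knockout 2 (0.0861), or with only numbers 1 to 3 (0.0504). Of 25 endothelial, 21 smooth muscle, 24 leukocyte and 11 erythroid markers 0 were called by limma, also adjusted over the list alone; 0, 2, 7 and 0 of them had an unadjusted p under 0.05. With the replicate block Car4 (endothelial, log2 change 0.32, adjusted p = 0.0172), Cnn1 (smooth muscle, -0.41, 0.0275), Laptm5 and Ccr2 (leukocyte, -0.27, 0.0227, and -0.33, 0.0282) and Slc4a1 (erythroid, 0.22, 0.0461) were called. Of 7 lymphatic markers, Tbx1 fell by 0.43 (1 adjusted over the list alone). Of 11 mesothelial markers, Krt19 rose by 0.67 and Msln by 0.46; with the block 2 rose and 1 fell (Upk3b, -0.26, adjusted p = 0.0271), and adjusted over the list alone, 2 rose and 1 fell. Of 12 neuroendocrine markers, Pcsk1 was called higher, with means of 5.92 and 6.35 and not when floored at 6.3 (adjusted p = 0.549), and Ddc fell by 0.47. With the block 1 rose and 2 fell, Scg2 (-0.24, adjusted p = 0.0392) among them, and adjusted over the list alone 1 rose and 2 fell. Of 16 markers of neurons, glia and muscle, S100b was called higher (1 adjusted over the list alone), but not with the block (adjusted p = 0.0825), and both its means (5.50 and 5.69) lay under 6.3.

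Taken as 1 mean per lung, 0 of 14 cell type lists differed after adjustment and 4 had an unadjusted p under 0.05 (exact permutation test). As the smallest p of this test is 0.0079, a single list cannot pass adjustment over 14 lists, so the count of 0 is weak evidence of no change. The basal list came closest, at 0.25 higher in the knockout (exact p = 0.00794, adjusted p = 0.0741), and rested on Krt15: the other 8 members averaged 0.06 (exact p = 0.0635). The club list was -0.24 and the ciliated list -0.10, each with exact p = 0.0159 and adjusted p = 0.0741. Within the same-numbered pairs, the basal list was higher in 5 of 5 (0.228 to 0.285), and the club (-0.366 to -0.01) and ciliated lists (-0.148 to -0.08) were lower in 5 of 5; exact sign flips within 5 pairs cannot give a p under 0.0625. By limma on the list means, chosen after seeing the data, 4 of 14 lists were called with the replicate block: basal (adjusted p = 3.15e-05), club (0.00473), ciliated (0.00909) and lymphatic (-0.11, 0.0283). The same test without the block also called these 4, at adjusted p = 0.0386 or less. For the full lists the count therefore changed with the test and not with the pairing. Without each list's member of the largest change, also chosen after seeing the data, limma with the block called 2 lists. These were club without Chad (-0.18, adjusted p = 0.0339) and ciliated without Myb (-0.09, 0.0405). Basal without Krt15 (0.06, adjusted p = 0.178) and lymphatic without Tbx1 (-0.06, 0.266) were not called with the block. Limma without the block called neither club (adjusted p = 0.0633) nor ciliated (0.131) in this form, so these 2 calls rest on the pairing. Without knockout 5, whose AT2 mean was -0.15 against a knockout mean of 0.05 ± 0.12 (SD, n = 5), 5 lists passed (exact permutation test, each adjusted p = 0.0444). They were AT2 (0.15) and basal (0.24), which were higher, and club (-0.24), ciliated (-0.12) and smooth muscle (-0.08), which were lower; this omission was singled out after seeing the data.

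TGF-beta genes moved both ways. Of 26 ligands, receptors and mediators, Smad3 rose by 0.36 ± 0.05 (SE), and Ltbp1 and Tgfb3 fell by 0.33 ± 0.07 and 0.23 ± 0.05. Tgfbr2, with a log2 change of 0.04 ± 0.07, and Tgfb1, with -0.08 ± 0.07, were not called. Of 25 response genes, Id1, Id3 and Junb rose by 0.63, 0.71 and 0.60, and the cell cycle inhibitor Cdkn2b fell by 0.64 ± 0.05. Neither list was shifted in 1 direction (camera adjusted p = 0.676 and 0.869). Camera does not test for changes of mixed direction. Fry's mixed test, which does but sets no list against other genes, gave adjusted p = 3.04e-10 and 1.74e-07. It was also low for other lists, such as AT1 markers (adjusted p = 1.12e-09), so it does not set the TGF-beta lists apart. With the block, 3 components rose and 2 fell, and 4 response genes rose and 2 fell, Ccn2 (-0.35, adjusted p = 0.0435) being the added fall. Adjusted over the list alone, 2 components rose and 2 fell, and 3 response genes rose and 1 fell. The study chose this pathway on these samples, so these counts are not independent evidence.

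The miR-17-92 list also holds microRNAs of paralogous loci, such as Mir106b and Mir106a, so its counts and median are not those of the cluster alone. Of its 16 members 6 were measured. Mir20a was called higher (adjusted p = 0.00112), but both its means (5.12 and 5.71) lay under 6.3. Mir17 had a log2 change of 0.30 (adjusted p = 0.0943, and 0.035 with the replicate block). With the block 3 members rose, and adjusted over the list alone 3 rose. The list was higher (camera adjusted p = 0.00967; adjusted p = 0.549 with an estimated correlation), with a median change of 0.31, and was not called once values were floored at 6.3 (adjusted p = 0.564). The study chose this cluster on these samples, so the count is not independent evidence.

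In the list of the corepressor complex and class I histone deacetylases, Tbl1xr1 rose by 0.26 and Tbl1x by 0.17 (0.0655 adjusted p with the block), while Hdac3 fell; of 10 measured members, 2 rose and 1 fell, also adjusted over the list alone. Of 27 adhesion, actin and basement membrane genes, 3 rose, also adjusted over the list alone: Ezr, the cortical linker ezrin, by 0.66 ± 0.08 (SE), Lama5, a laminin chain, by 0.41 ± 0.06, and Actn4 by 0.19 ± 0.05 (blocked adjusted p = 0.0571). That list was not shifted (camera adjusted p = 0.322). Of 17 Hippo-YAP target genes 0 were called by limma and 6 had an unadjusted p under 0.05; Axl stood at -0.21 (adjusted p = 0.072, and 0.0373 with the block) and F3 at 0.48 (0.218, and 0.0204 with the block), and with the block 1 rose and 2 fell. The Hippo-YAP list was lower (camera adjusted p = 0.0133; adjusted p = 0.388 with an estimated correlation), but not with only numbers 1 to 3 (adjusted p = 0.0504) or 4 and 5 (0.0597), and 1 member fell adjusted over the list alone. Of 16 elastic fibre genes 0 were called by limma, also adjusted over the list alone, and 3 had an unadjusted p under 0.05.

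Among metabolic and stress lists, cholesterol synthesis was higher (camera adjusted p = 0.0116; adjusted p = 0.549 with an estimated correlation) but not without knockout 1 (adjusted p = 0.0518) or with only numbers 4 and 5 (0.0517). Of its 14 genes Hmgcs1, at the entry to the pathway, rose by 0.48 ± 0.10 (SE); with the block 2 rose, and adjusted over the list alone 1 did. Of 25 hypoxia and stress genes, Nqo1 rose by 1.04 and Asns, asparagine synthetase, by 0.60, with 5 rising and 1 falling (Pdk1, -0.25, adjusted p = 0.0314) under the block; adjusted over the list alone 3 rose and 1 fell. That list was higher (camera adjusted p = 0.0294; adjusted p = 0.549 with an estimated correlation). The call ended without control 4 (adjusted p = 0.095), control 5 (0.0745), knockout 1 (0.0617) or knockout 2 (0.0653). It also ended with every probe set (0.0531), genes above the median level (0.135), values floored at 6.3 (0.0554) and only numbers 1 to 3 (0.111). Of 26 lipid genes 0 were called by limma and 8 had an unadjusted p under 0.05; with the block 3 rose, among them Gpam (0.30, adjusted p = 0.029) and Acaca (0.23, adjusted p = 0.0423), and 1 fell (Lpin1, -0.22, adjusted p = 0.0358), and adjusted over the list alone 3 rose. Of 18 fatty acid oxidation genes 0 were called, also adjusted over the list alone, and 3 had an unadjusted p under 0.05.

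Of 26 proliferation genes 0 were called by limma, also adjusted over the list alone, and 0 had an unadjusted p under 0.05. Their median change was 0.16, but 0.0649 without control 4, 0.103 without knockout 1 and 0.0605 without knockout 5. The list was higher (camera adjusted p = 0.0116, and 0.895 with an estimated correlation). The call ended without control 4 (adjusted p = 0.383), knockout 1 (0.129) or knockout 5 (0.48), with array weights (0.114), with the Y-linked level as covariate (0.116) and with only numbers 1 to 3 (0.98). Of 21 cell cycle inhibitors and p53 response genes, Btg2, an antiproliferative gene, rose by 0.71 ± 0.07 (SE) and Cdkn2b fell by 0.64 ± 0.05, also adjusted over the list alone; with the block 2 rose, Cdkn1a (0.43, adjusted p = 0.00265) being added, and 1 fell.

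Of 19 cytokine and chemokine genes, Saa3, an acute phase protein, rose by 0.92 ± 0.17 (SE) and Il18 fell by 0.42 ± 0.08; with the block 4 rose and 1 fell, 3 rose and 1 fell without knockout 5, and adjusted over the list alone 5 rose and 1 fell. Of 17 glucocorticoid and maturation genes, Scnn1b, a subunit of the epithelial sodium channel, fell by 0.61 ± 0.06 and Mt1 rose by 0.57 ± 0.13; with the block 2 rose and 1 fell, and adjusted over the list alone 2 rose and 1 fell. Of 14 Wnt targets, Znrf3 rose by 0.24 and Lgr5 fell by 0.36, also adjusted over the list alone. The knockout means of Lgr5 (6.24) and Il18 (6.286) lay under the 20th percentile of all values (6.3). With values floored there their changes were -0.295 and -0.347, and both were still called (adjusted p = 0.00251 and 0.0299). Of 20 interferon, 15 Notch and 11 imprinted growth genes 0 were called by limma, also adjusted over the list alone, and 0 had an unadjusted p under 0.05. None of the lists in this paragraph was shifted; the lowest camera adjusted p was 0.225. With only numbers 4 and 5, a subset chosen after seeing the data, the interferon list turned from a median of -0.03 to 0.11 and was called higher (camera adjusted p = 0.00543).

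**Figure D2:**
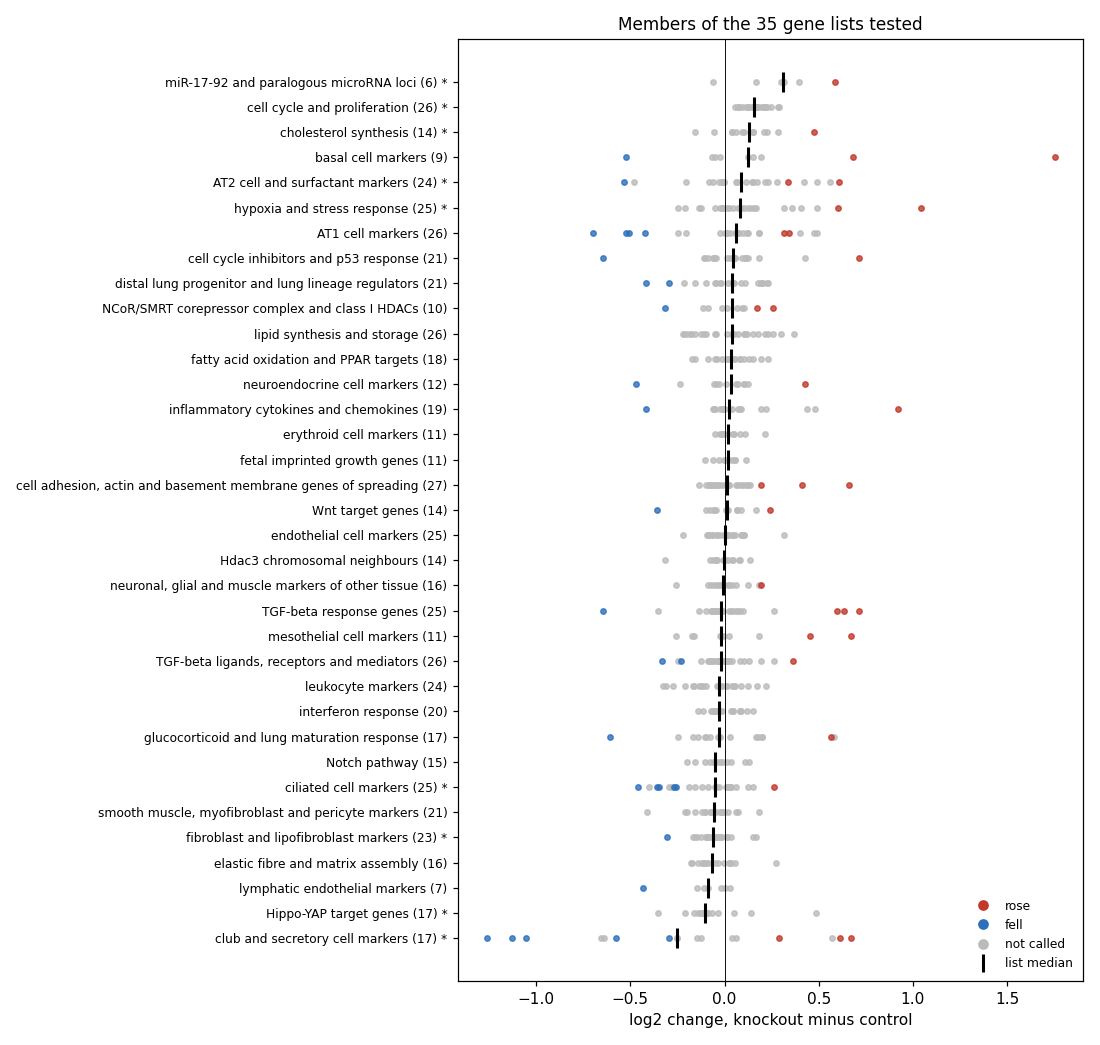
Each point is the log2 change (knockout minus control) of 1 member of a gene list, red where it rose, blue where it fell and grey where it was not called; black bars are list medians, numbers in brackets count measured members, and asterisks mark camera adjusted p under 0.05 at the preset correlation. The medians run from -0.25 for club cell markers to 0.31 for the list of miR-17-92 and paralogous microRNA loci. With an estimated correlation 0 lists pass.

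A group outside the naming rule was singled out after its values were seen. Of 286 microRNA precursor genes, 42 rose and 2 fell, so that 15.2% of all rises were microRNA precursors. Between Dlk1 and Dio3, an imprinted domain, by the gene order of GRCm38.p6, 37 of 43 precursors rose (40 with the replicate block) and 0 fell, against 5 that rose and 2 that fell among 243 elsewhere. The median change in the domain was 0.84, a fold of 1.78, and the domain's mean was 0.86 higher in the knockout, with SD 0.13 in controls and 0.12 in knockouts (n = 5 each, exact permutation p = 0.00794). The domain was chosen for these rises, so this p is not independent evidence. Each probe set reads the polyadenylated RNA that contains its precursor, so neighbouring precursors may read the same RNA. The 43 may therefore not be separate results. Mir376b and Mir376a rose most, by 1.64 ± 0.09 and 1.63 ± 0.06 (SE). Of 6 long transcripts of the domain, Rian rose by 0.36 ± 0.05, while Meg3 (0.12 ± 0.08) and Dlk1 (-0.06 ± 0.06) were not called; 3 of 5 small nucleolar RNAs rose, with a median of 0.43 over the 5.

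**Figure D3:**
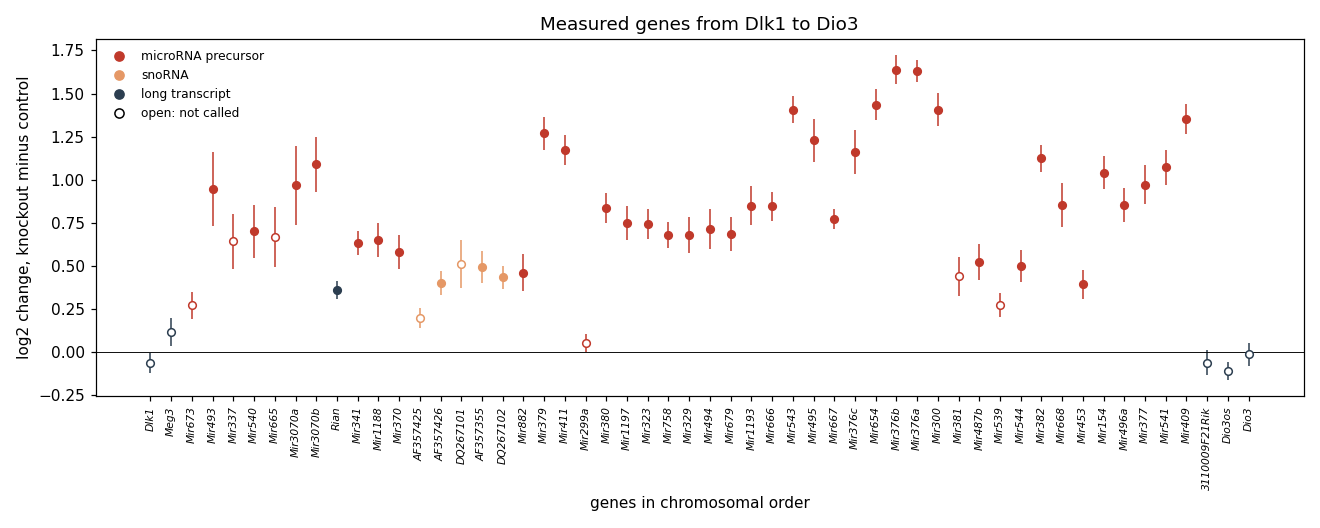
Log2 change (knockout minus control, bars SE, n = 5 per group) of each measured gene from Dlk1 to Dio3 in chromosomal order, with microRNA precursors in red, small nucleolar RNAs in orange and long transcripts in dark blue; open circles were not called. The precursors lie between 0.055 and 1.64, and 37 of 43 were called.

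At the preset correlation camera called 9 of 35 lists, and the lowest adjusted p among the other 26 was 0.0587, for the lymphatic, smooth muscle and elastic fibre lists. These and the leukocyte list passed without knockout 3 (adjusted p = 0.0289 or 0.029), all as lower, and each passed in other settings too. With an estimated correlation 0 lists passed and 1, the Hippo-YAP list, had an unadjusted p under 0.05. Fry's test for 1 direction, which does not compare a list with other genes, called 2 (Hippo-YAP and basal cell markers). Of 68 called genes that the rule named besides Hdac3, 53 were called in all 10 fits that each left out 1 lung, and Actn4, Ddc, Dnaic2, Fgfr2, Foxa1, Gclc, Hmgcs1, Ltbp1, Mt1, Myb, Pcsk1, S100b, Slc7a11, Tbl1x and Tgfb3 were not, with highest adjusted p from 0.051 (Gclc) to 0.121 (S100b). Besides the genes near 6.3 given above, flooring ended the calls of Ddc, Foxa1, Gclc, Hmgcs1, Ltbp1, Mt1 and Myb (adjusted p from 0.0569 to 0.113). Of these only Ddc had lungs under 6.3. The values and changes of the others stayed the same, so their calls ended through the effect of flooring on other genes in the fit and adjustment. Counts of list members also moved when 1 lung was left out. Without knockout 5, rises went to 3 for TGF-beta ligands, receptors and mediators, 4 for hypoxia and stress (and 1 fall), 2 for cholesterol synthesis, 2 for glucocorticoid response and 1 each for lipid and Hippo-YAP genes, while falls went to 6 for ciliated, 7 for club, 2 for neuroendocrine and 1 for smooth muscle markers. Over all 10 such fits, ciliated falls ran from 2 (without knockout 3) to 6. Falls ran from 1 to 2 for distal regulators and from 0 to 2 for neuroendocrine markers and TGF-beta ligands, receptors and mediators, and rises from 0 to 2 for cholesterol synthesis and glucocorticoid response.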

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

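The tests of a failed array were chosen after the sample correlations were seen, and that of the X chromosome before its result. In 278 groups of 5 lungs, 18 had 1 value far from the other 4, where chance gives about 14, so this number alone lies close to what chance gives.

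Sex-linked transcripts set knockout 5 apart. Xist, expressed from an inactive X chromosome, was 11.21 in control 1 and 11.47 in knockout 1, each far from the other lungs of its group (5.13 and 5.06 the nearest), and control 1 had a sex-linked list mean of -1.38 against 0.73 for the nearest. Knockout 5 had low Xist (4.96) and a low mean of Y-linked genes (4.96), while 7 lungs had Y-linked means of 9.54 or more. A single X chromosome with no Y may be the source: it predicted that 3 genes that escape X inactivation lie within the range of the 7 lungs with Y-linked transcripts. Their mean in knockout 5 was 10.259, just above that range (10.155 to 10.257) and below both lungs with Xist (10.486 and 10.524), so the test did not decide. The lowest correlation of knockout 5 with its group was 0.9887, just below the 0.9895 to 0.9953 among the other knockouts. The limit for a failed array was set after the correlations were seen, so this test does not decide whether the array was poor. A sample from outside the groups was not tested.

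Single lungs also stood apart for named genes. Among controls, Cxcl3 was 3.96 in control 4 (nearest 4.44), Aqp3 6.18 in control 5 (nearest 6.49), Npnt 11.94 in control 5 (nearest 12.02), Tbl1x 10.53 in control 4 (nearest 10.49), Oasl1 7.25 in control 3 (nearest 6.81) and Il18 6.91 in control 2 (nearest 6.69). Among knockouts, Retnla was 8.23 in knockout 5 (nearest 9.04), Reg3g 6.20 in knockout 3 (nearest 5.39), and Hc and Pdpn were 10.80 and 10.08 in knockout 4 (nearest 9.62 and 9.63). List means stood apart for leukocyte markers in control 5 (-0.04, nearest 0.03), TGF-beta ligands, receptors and mediators in knockout 5 (-0.08, nearest 0.01), and 3 lists in knockout 4: fatty acid oxidation (-0.056, nearest 0.021), elastic fibre (-0.104, nearest -0.014) and imprinted growth genes (-0.082, nearest 0.017).

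Among 5966 probe sets with no gene name or several, which were used above only in the alternative with every probe set, 66 were higher and 25 lower in the knockout. Of these, 25 higher and 6 lower probe sets carry several gene names.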

How the results depend on the processing

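The block and subsets of numbers 1 to 3 and 4 to 5, which the second principal component set apart in both groups, the replicate block with an estimated correlation, limma on list means and the omission of each list's member of the largest change were chosen after seeing the data. From 559 genes (276 higher, 283 lower), the count moved to 846 (437 lower) with the replicate block fixed, 949 (468 higher, 481 lower) with it random, and 910 (455 higher, 455 lower) with numbers 1 to 3 and 4 to 5 as a block. It was 2 (1 higher, 1 lower) with only numbers 4 and 5, where 4 lungs remain, and 188 genes were lower with only numbers 1 to 3. It was 261 (129 higher, 132 lower) at adjusted p under 0.01 and 139 (84 higher, 55 lower) at a fold of at least 1.5. The exact Wilcoxon test called 0 genes (0 higher, 0 lower): its lowest adjusted p was 0.155, with 1890 genes at unadjusted p under 0.05 (limma: 2428), and 916 genes at its smallest p against 142 by chance. Leaving out 1 lung gave 393 (without control 1) to 699 (without knockout 5) genes, 189 to 382 higher and 202 to 317 lower. Lists shifted went from 9 to 5 with genes above the median level, 5 with only numbers 1 to 3, 2 with fry, 0 with an estimated correlation and 0 with the replicate block and an estimated correlation; leaving out 1 lung gave 3 (without knockout 1) to 12 (without control 1 or knockout 3), and 5 without control 4. The random block gives camera no value. Hdac3 was -0.26 with only numbers 1 to 3 (adjusted p = 0.0629), -0.40 with only numbers 4 and 5 (0.421), and -0.35 to -0.28 without 1 lung; it has 1 probe set, so no other was tried. Cell type lists by mean stayed at 0 by the exact test, except 5 without knockout 5. In that test a single list cannot pass adjustment over 14 lists, so the 0 is weak evidence of no change. Limma on the list means called 4, both with the replicate block and without it. With each list's member of the largest change left out, limma called 2 with the block. The lowest adjusted p of limma without the block was then 0.0633, and the exact test stayed at 0. The interferon list turned from -0.03 to 0.11 with only numbers 4 and 5 and was called there (adjusted p = 0.00543). Subsets hold fewer lungs, which may add to the losses there. Neither this nor the cause of the other moves was tested. Of 101 named genes besides Hdac3, 0 reversed under any setting. The fixed replicate block ended 3 calls and added 10, and it changed no list's call. Flooring ended 13 calls, some of them, such as that of Gclc, in genes with 0 lungs under 6.3. Dim probe sets limit some values: flooring at the 20th percentile (6.3) ended the miR-17-92 list's call, and 30 precursors between Dlk1 and Dio3 rose with it against 37 without.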

Other observations

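The tests of the microRNA precursors outside the domain and of its other transcripts were chosen after related values were seen; the other tests in this part were set before their results.

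Genes of the NRF2 antioxidant response formed a further group, listed after the data were seen. Of 32 measured targets 7 rose and 0 fell, and 10 rose with the replicate block; Slc7a11, among the 7, lay under the 20th percentile of all values (6.3) in both group means. Nfe2l2, which encodes NRF2, rose by 0.41, Srxn1, a sulfiredoxin, by 0.93, Gsr, glutathione reductase, by 0.37 and the glutathione transferase Gsta3 by 0.67. Hmox1, a common NRF2 target, was at 0.09 and not called. The mean of the list was 0.26 higher in the knockout, with SD 0.06 in controls and 0.13 in knockouts (n = 5 each, exact permutation p = 0.0159), and knockout 5 (-0.10) lay within the range of the controls (-0.21 to -0.05). The list holds 5 targets seen beforehand, so this p is not independent evidence.

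A hypothesis from Gclc and Nqo1 is that NRF2 targets rise as a group. The 27 targets not seen beforehand among the called genes had a median change of 0.094 (camera p = 0.000137, and p = 0.114 with an estimated correlation), and 3 of them rose. Gclm and Hmox1, among the 27, also belong to the hypoxia and stress list described above, so the 27 are not fully independent of earlier results. The prediction was met at the preset correlation only. A single lung is argued against as the source, since the lowest median of the list without 1 lung was 0.096 (without knockout 1) against 0.103 with all. Whether oxidative stress, Hdac3 loss itself or a change of cell types may be behind it was not tested.

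The rise of microRNA precursors between Dlk1 and Dio3 may be a change of the domain itself. A rise of all precursor probe sets is argued against, as the median change outside the domain was 0.031 against 0.836 inside, and 0.015 among the 145 outside with a mean above 6.3. A single lung is argued against, as the lowest median without 1 lung was 0.766. More cells that express the whole domain cannot be told apart from it: the 6 long transcripts had a median of -0.037, but they went both ways and Dio3, Dio3os and 3110009F21Rik lay near or under 6.3, while Rian rose by 0.36 and the 5 small nucleolar RNAs had a median of 0.434, over 0.5 of the precursors' median (0.197 with both kinds pooled). Transcription or processing of the maternal transcripts also stays open and untested, and mature microRNAs were not measured here.

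Chance splits of the lungs were also counted. Of 100 splits of the 10 lungs into 5 and 5, 1, the real one, called as many genes: 559 against at most 3 in another. This argues against chance only where the lungs are taken as unpaired, since these splits ignore the replicate numbers. Of the 16 splits that part every same-numbered pair, 1, the real one, called 559 genes and the others 0. As 16 splits are too few for a share under 0.05, they cannot exclude chance where the numbers are taken as pairs. For gene lists, 5 of 100 splits called at least as many as the real 9, with 11 as the highest other, so chance cannot be excluded for the number of lists called at the preset correlation. These splits also ignore the replicate numbers, and no list count is given for the 16 splits that part every pair.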
